A study of Homo sapiens with 21 samples.

How the data were processed

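Total RNA from 21 samples was sequenced in bulk, with 3 libraries each of undifferentiated iPSCs and of EBs at days 0, 2, 4, 6, 8 and 10. Per the labels, aggregates were made on day 0 and moved the next day to suspension dishes, and the libraries were paired-end and made with the Lexogen CORALL RNA-Seq V2 kit. Whether the 3 replicates of a group are separate cultures or technical repeats was not given in the sources used here, nor was the hour at which the EB day 0 samples were collected. All column names carry the same lane number and the sample sheet numbers run on within a replicate number.

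The deposited count table holds whole-number counts per gene that had not been normalized, and the submitters' processing notes name STAR, Salmon and the build GRCh38 without versions. The deposited gene-level estimated counts, not all of them whole numbers and not scaled to depth, are of the kind that Salmon gives and are called Salmon estimates in the text. A further deposited table gives counts of reads assigned to no gene. From it came the shares with no annotated feature (no-feature) and in more than 1 gene (ambiguous, 3.61% to 6.84%). Whether no-feature reads lay between genes or in introns was not given. The annotation release and the strand setting were not given in the sources used here. Ambiguous reads go to no gene, so close paralogs and overlapping genes lose or share counts. The rounded copies of the estimates, the tables in TPM and the transcript tables were not used here, and no isoforms were analysed here.

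The 38592 gene IDs of the count table were given symbols from the table (38568 IDs) and a biotype and place from GENCODE 29 (34390 IDs), or a biotype from a RefSeq table by symbol (352 IDs). The choices of test, groups, gene lists, named genes and most alternative settings were fixed before the data were examined. Groups followed the labels, and 7 comparisons were made: EB day 0 against iPSC, each EB day against the day before it in the series, and EB day 10 against EB day 0. All 21 libraries entered 1 fit in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood test, 1 mean per group, no block). This left 24301 genes, and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05 in each comparison. A joint test of days 2 to 10 against day 0 served the time course. A gene was called transient when its highest EB mean fell on day 2, 4, 6 or 8 and lay at least 2-fold above both day 0 and day 10, each past the threshold.

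Of 39 gene lists, 38 had at least 5 tested members and were tested with camera in limma 3.58.1 (preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the lists of each comparison. Beside the count of members passing among all genes stands the count when p is adjusted over the list alone. Camera with an estimated correlation is given beside each called list. Levels are CPM on TMM-scaled library sizes.

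Named genes followed a rule. They were the 10 with the largest rise and the 10 with the largest fall for EB day 0 against iPSC and for day 10 against day 0, and 5 and 5 for the other comparisons. These had to pass the threshold, be protein-coding, have a mean of at least 5 CPM in the higher group and show no overlap of libraries between the groups, which chance gives for 10% of genes with 3 libraries against 3. Further named genes were up to 4 members of each described list with the smallest p, other members that moved against their list or did not pass, 14 profile genes, and the 5 transient genes per peak day with the largest fold over the higher end. Mitochondrially encoded and sex-linked marker genes were left out of the first part. Results for some further genes are not reported here. Metallothioneins and other genes named in a comparison where the rule does not give them, and SLC30A1, ZIC2, PTPRZ1 and MGAT2 in the closing section, were chosen after their values were seen.

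Pairing by replicate number was checked by correlating, across genes, the deviations of same-numbered libraries from their group means. A comparison was taken as paired when all 3 correlations passed 0.1, which held for days 2 against 0 (0.163 to 0.311), 4 against 2 (0.25 to 0.548), 6 against 4 (0.176 to 0.643) and 8 against 6 (0.148 to 0.637). It did not hold for EB day 0 against iPSC (lowest -0.073), day 10 against 8 (0.546, 0.096 and 0.468) or 10 against 0 (lowest -0.065). For paired comparisons a fit with the replicate number as a block is given where it changed a call.

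The fits were tested on simulated data in which 200 of 21377 genes were changed between EB days 2 and 0. Of 50 genes changed 2-fold upward 62% were recovered, of 50 changed 4-fold 98%, and of those lowered to 0.5 and 0.25 of their level 70% and 96%. A further 12 genes were changed as members of 1 list, with 7 false calls among 21165 unchanged genes. Of 50 transient genes 47 were recovered, and that list alone was called. No correlation within lists was simulated, so this cannot vouch for list calls. A structure shared by same-numbered libraries was not simulated either. The median SD between replicates on the log2 scale ran from 0.206 in iPSCs to 0.35 at EB days 0 and 8. No 2 replicates were copies of each other (chi-square per gene 7.62 to 139, genes with at least 20 counts).

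Alternative settings fixed in advance were DESeq2 1.42.0 (Wald test, and a likelihood ratio test for the time course), RLE factors, no low-count filter, a stricter filter, the replicate block, a fit of the compared libraries alone, the rounded Salmon estimates, each library left out in turn, and for lists an estimated correlation and fry. Added after the data were seen were the block with the no-feature share as a covariate and a fit without all replicate 1 libraries.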

Results

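Gene expression was measured by bulk RNA sequencing in 21 libraries from a time course of embryoid body (EB) differentiation, in which pluripotent cells are aggregated and leave the pluripotent state in suspension culture. The cells were KOLF2.2J, an established human induced pluripotent stem cell (iPSC) line, here carrying a doxycycline-inducible CRISPR interference cassette at the AAVS1 locus. The libraries formed 7 groups of 3: undifferentiated iPSCs and EBs at days 0, 2, 4, 6, 8 and 10. Each library held between 22697002 and 37864199 counts in genes. At this depth 3 counts over the 3 libraries of a group, taken as the floor of detection, correspond to between 0.0318 and 0.0405 CPM (counts scaled to a common library size), and intervals and floors cover counting error only. Levels below are CPM as mean ± SD over 3 libraries (n = 3), with the earlier group first. Genes were tested with edgeR over 24301 genes, and 38 fixed gene lists were tested with camera.

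The groups followed the order of time along the first principal component, which held 56.3% of the variance. From day 2 on, the replicate 1 library of each day lay nearer to the iPSC libraries than replicates 2 and 3 did. On that component EB day 2 replicate 1 scored -63.15 against -27.45 and -27.01, EB day 8 replicate 1 scored 27.67 against 93.46 and 127, and EB day 10 replicate 1 scored 91.38 against 150.8 and 148.8. These libraries also had a lower share of reads assigned to no annotated feature (the no-feature share). It was 22.85% on day 2 against 35.95% and 36.75%, and 24.29% on day 6 against 39.95% and 48.45%. The group mean of this share was 19.92% ± 1.48 in iPSCs and 43.24% ± 4.29 at EB day 10 (SD, n = 3).

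**Figure D1:**
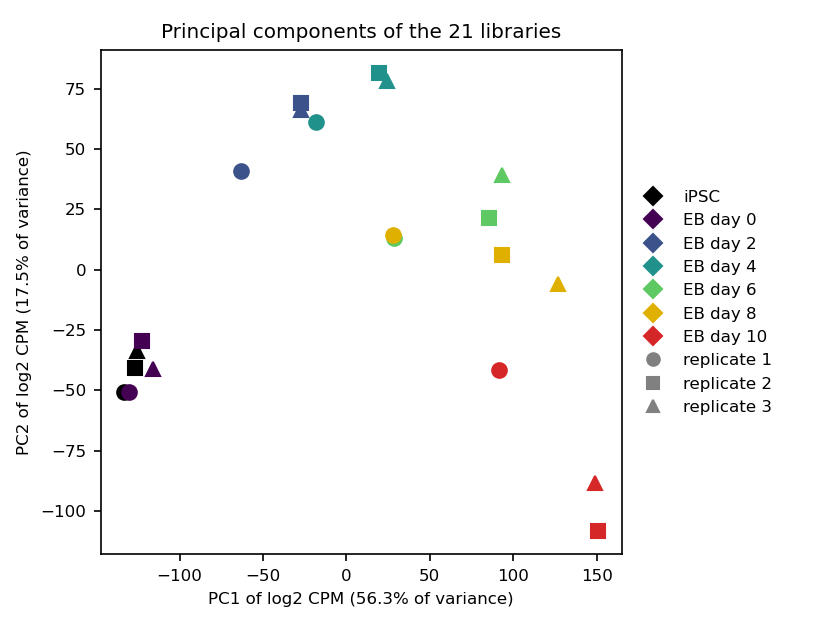
Each point is a library on the first (56.3% of variance) and second (17.5%) principal components of log2 CPM, coloured by group and marked by replicate number. The iPSC and EB day 0 libraries lie together, and replicate 1 of EB days 2 to 10 lies at lower values of the first component than replicates 2 and 3 of the same day.

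**Figure D2:**
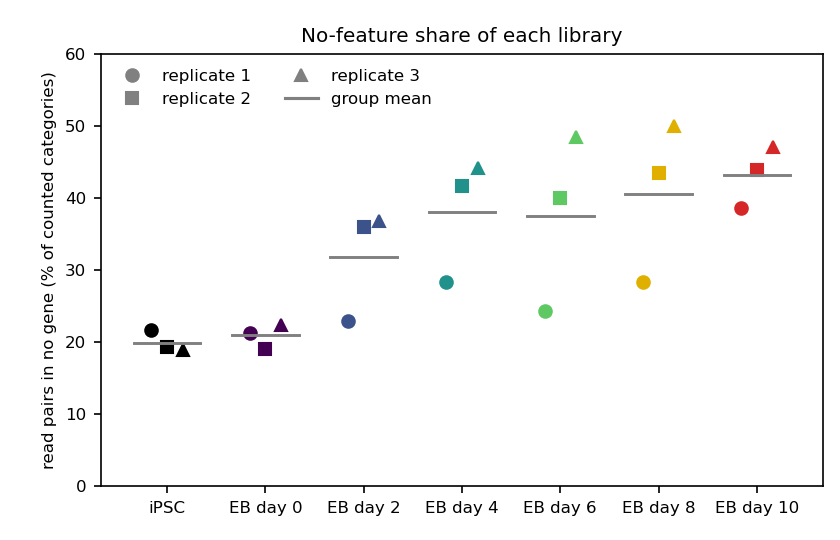
The share of reads assigned to no annotated feature, in percent, is plotted for each library by group, with bars at the group means. The means run from 19.92% in iPSCs to 43.24% at EB day 10, and replicate 1 is the lowest library at days 2, 4, 6, 8 and 10.

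EB day 0, sampled at an hour not given, was compared with iPSCs. Metallothioneins, small proteins that bind zinc and copper, made up 7 of the 10 named genes with the largest rise, though they were not a list fixed beforehand. MT1G (ENSG00000125144, chromosome 16, 56666731 to 56668065) rose from 3.62 ± 0.92 to 440 ± 180 CPM (log2 fold change 6.93, SE 0.68, adjusted p = 2.45e-05). MT1H rose from 0.838 ± 0.016 to 103 ± 48 and MT1E from 2.57 ± 0.69 to 243 ± 140 CPM. MT2A rose from 1.3 ± 0.16 to 50.4 ± 17 and MT1F from 1.03 ± 0.15 to 29 ± 6.2 CPM. MT1X rose from 13.1 ± 3.5 to 69.9 ± 19 and MT1M from 0.0807 ± 0.073 to 6.31 ± 2.9 CPM. These genes are close paralogs lying side by side on chromosome 16, so the separate count of each is uncertain. JUN, an immediate early transcription factor, rose from 11 ± 0.25 to 51 ± 12 CPM (log2 fold change 2.21, SE 0.30, adjusted p = 0.000829). SYNDIG1L and GLIPR1L1 rose from 3.25 ± 0.57 to 19.6 ± 12 and from 2.08 ± 0.63 to 8.26 ± 2.8 CPM.

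Of the list of hypoxia and glycolysis genes, which respond to low oxygen or carry out glucose breakdown, 5 of 20 rose and 15 did not pass (14 adjusted over the list alone, camera adjusted p = 5.34e-13, adjusted p = 0.0244 with an estimated correlation). BNIP3, a receptor for removal of mitochondria, rose from 245 ± 24 to 492 ± 110, and ADM, which encodes the vasodilator adrenomedullin, from 28.3 ± 5.2 to 81.1 ± 7.9 CPM. PFKFB3, a regulator of glycolysis, rose from 48.5 ± 8.8 to 102 ± 44 CPM. Targets of NODAL, the signal that patterns the early embryo, moved the other way: 3 of 10 fell and 7 did not pass (4 adjusted over the list alone, camera adjusted p = 2.66e-06, adjusted p = 0.0366 with an estimated correlation). LEFTY2 and LEFTY1, paralogous inhibitors of NODAL whose separate counts are uncertain, fell from 2.59 ± 0.61 to 0.145 ± 0.049 and from 2.62 ± 0.67 to 0.209 ± 0.18 CPM. CER1 fell from 0.655 ± 0.23 to 0.079 ± 0.034, and NODAL itself measured 6.45 ± 0.68 and then 3.04 ± 0.27 CPM (adjusted p = 0.115). In the integrated stress and unfolded protein response list, 1 of 16 fell and 15 did not pass (5 adjusted over the list alone, camera adjusted p = 1.07e-07, adjusted p = 0.0537 with an estimated correlation). ATF4, the transcription factor of amino acid shortage, fell from 628 ± 19 to 314 ± 84 CPM, and the glutathione-degrading enzyme CHAC1 measured 26.9 ± 1.6 and then 9.3 ± 1.2 CPM (adjusted p = 0.0621).

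Among other large falls, the amino acid transporter SLC7A5 fell from 136 ± 46 to 31 ± 12, INHBE, an activin subunit, from 14.8 ± 0.68 to 3.34 ± 0.91, and the matricellular protein CCN2 from 27.9 ± 5.5 to 6.79 ± 2.3 CPM. The Notch ligand DNER fell from 7 ± 0.66 to 1.37 ± 0.19 and HHLA1 from 19.7 ± 3.5 to 2.22 ± 0.38 CPM. SERPINB9, an inhibitor of granzyme B, fell from 68.1 ± 5.1 to 21.1 ± 1.2 and RGS5 from 26.6 ± 0.49 to 7.36 ± 1.9 CPM. STOX2 fell from 32.4 ± 1.2 to 8.82 ± 2.4 and COLEC12 from 7.79 ± 0.48 to 1.86 ± 0.43 CPM. GFI1B, a blood transcription factor, fell from 18.4 ± 16 to 2.61 ± 0.23 CPM, with iPSC libraries at 16.6, 3.78 and 34.8 CPM. In all, 74 genes rose and 96 fell (edgeR, adjusted p threshold 0.05), 53 and 71 of them by at least 2-fold. The counts were 19 and 33 without iPSC replicate 2 and 214 and 153 without EB day 0 replicate 1. Without all replicate 1 libraries they were 728 and 822.

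Between EB day 0 and day 2, the interval that holds the transfer to suspension culture, hypoxia and glycolysis genes were lower: 18 of 20 fell and 2 did not pass (18 adjusted over the list alone, camera adjusted p = 2.02e-13, adjusted p = 0.0213 with an estimated correlation). BNIP3 fell from 492 ± 110 to 48.2 ± 5.3 and the glucose transporter SLC2A1 from 933 ± 290 to 157 ± 21 CPM. PFKFB4 fell from 56.4 ± 23 to 7.03 ± 0.84 and MT1X from 69.9 ± 19 to 1.73 ± 0.28 CPM. The other metallothioneins fell as well, MT1G from 440 ± 180 to 0.89 ± 0.042, MT1E from 243 ± 140 to 0.665 ± 0.26 and MT1H from 103 ± 48 to 0.317 ± 0.19 CPM. MT1M had 1 count at day 2, a ratio of 616 (95% interval 110 to 24400). DUSP6, a phosphatase that is a standard readout of FGF and ERK signalling, fell from 67.4 ± 10 to 0.276 ± 0.051 CPM (log2 fold change -7.91, SE 0.45, adjusted p = 4.13e-10). Of the FGF and ERK targets, 8 of 14 fell and 6 did not pass (8 adjusted over the list alone, camera adjusted p = 5.52e-05, adjusted p = 0.218 with an estimated correlation). DUSP5 fell from 20.6 ± 2.9 to 3.86 ± 0.41 and PHLDA1 from 92.9 ± 31 to 17.4 ± 0.65 CPM. IER3 fell from 5.12 ± 1.6 to 0.94 ± 0.3 CPM.

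Genes of BMP signalling and of non-neural ectoderm rose over the same interval. TFAP2A (ENSG00000137203, chromosome 6, 10393186 to 10419659), a transcription factor of surface ectoderm, amnion and neural crest, rose from 0.0848 ± 0.052 to 20.4 ± 1 CPM (log2 fold change 7.89, SE 0.61, adjusted p = 2.59e-08). Among BMP targets, 9 of 13 rose and 4 did not pass (9 adjusted over the list alone, camera adjusted p = 1.59e-07, adjusted p = 0.0528 with an estimated correlation). ID4 rose from 6.1 ± 1.5 to 91.4 ± 11 and GATA2 from 0.101 ± 0.094 to 4.52 ± 0.45 CPM. MSX2 rose from 0.175 ± 0.093 to 4.48 ± 0.59 and HAND1 from 0.16 ± 0.023 to 6.01 ± 0.93 CPM. For surface ectoderm, 7 of 11 rose, 1 fell and 3 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 8.46e-05, adjusted p = 0.202 with an estimated correlation). The epidermal regulator DLX5 rose from 0.057 ± 0.05 to 3.79 ± 0.44 and GRHL3 from 1.15 ± 0.23 to 24.1 ± 1.4 CPM. For amnion and trophoblast, 8 of 16 rose, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 0.00184, adjusted p = 0.38 with an estimated correlation). TFAP2C rose from 6.85 ± 3.5 to 48.6 ± 2.1 CPM. In the lateral and cardiac mesoderm list, 6 of 12 rose, 2 fell and 4 did not pass (6 and 2 adjusted over the list alone, camera adjusted p = 0.0141, adjusted p = 0.362 with an estimated correlation). BMP4 rose from 2.43 ± 0.39 to 49.7 ± 9.5 and ISL1 from 0.691 ± 0.25 to 9.02 ± 1 CPM, while MEF2C fell from 2.7 ± 0.026 to 0.424 ± 0.026 CPM. Hedgehog targets followed: 4 of 7 rose, 1 fell and 2 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.00286, adjusted p = 0.0606 with an estimated correlation). The receptor PTCH1 rose from 50.2 ± 12 to 660 ± 2.3, and HHIP, an inhibitor of the pathway, from 0.877 ± 0.36 to 22.5 ± 6 CPM. The forebrain factors LHX5 and SIX3 rose from 0.369 ± 0.064 to 43.6 ± 10 and from 0.121 ± 0.14 to 7.57 ± 2.5 CPM. The homeobox gene MEIS2 rose from 0.5 ± 0.19 to 31.4 ± 1.6, and EDN1, which encodes endothelin 1, from 0.505 ± 0.17 to 35.5 ± 5.9 CPM.

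The lists that tested lower were of several kinds. Of the endothelium and blood progenitor genes, 6 of 14 fell, 1 rose and 7 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.00621, adjusted p = 0.0528 with an estimated correlation). The VEGF receptor KDR fell from 302 ± 48 to 39.8 ± 8 and ERG from 20.4 ± 2.4 to 1.97 ± 0.14 CPM. TIE1 fell from 4.85 ± 1.8 to 0.264 ± 0.097 CPM. Of the neuron genes, 5 of 11 fell and 6 did not pass (6 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.348 with an estimated correlation). SYT4 fell from 20 ± 5.9 to 0.741 ± 0.13 and the tubulin TUBB3 from 157 ± 26 to 55.3 ± 12 CPM. Of the p53 targets, 10 of 16 fell, 2 rose and 4 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.0134, adjusted p = 0.473 with an estimated correlation). GDF15 fell from 4.34 ± 1.1 to 0.435 ± 0.053, and CDKN1A, the cell cycle inhibitor p21, from 15.5 ± 6.3 to 4.32 ± 0.64 CPM. Of the immediate early genes, 8 of 13 fell and 5 did not pass (8 adjusted over the list alone, camera adjusted p = 0.00762, adjusted p = 0.348 with an estimated correlation). MYC fell from 68.6 ± 13 to 16.4 ± 2.2 and FOS from 6.58 ± 0.92 to 1.67 ± 0.56 CPM. Of the cholesterol synthesis genes, 9 of 21 fell and 12 did not pass (10 adjusted over the list alone, camera adjusted p = 0.00527, adjusted p = 0.569 with an estimated correlation). MVD fell from 48.1 ± 5.5 to 16.9 ± 4 and FDFT1 from 324 ± 48 to 132 ± 32 CPM. Of the erythroid genes, 3 of 5 fell and 2 did not pass (3 adjusted over the list alone, camera adjusted p = 0.0401, adjusted p = 0.202 with an estimated correlation). AHSP, a chaperone of alpha globin, fell from 3.93 ± 1.4 to 0.305 ± 0.25 CPM. Mitochondrially encoded genes and histones served as markers of RNA quality. Of the former, 6 of 13 fell and 7 did not pass (8 adjusted over the list alone, camera adjusted p = 0.014, adjusted p = 0.595 with an estimated correlation). Of the replication-dependent histones, 2 of 15 fell and 13 did not pass (1 adjusted over the list alone, camera adjusted p = 0.0335, adjusted p = 0.642 with an estimated correlation).

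The calls of 4 more lists were lost with the replicate number as a block. In mesenchyme and extracellular matrix 6 of 20 fell, 1 rose and 13 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.0459, adjusted p = 0.348 with an estimated correlation, adjusted p = 0.0502 with the replicate block). THY1 fell from 671 ± 87 to 81.6 ± 25 CPM. In WNT targets 5 of 14 rose, 1 fell and 8 did not pass (5 and 1 adjusted over the list alone, camera adjusted p = 0.0402, adjusted p = 0.348 with an estimated correlation, adjusted p = 0.0595 with the replicate block). The WNT effector LEF1 rose from 0.922 ± 0.1 to 7 ± 0.69 CPM. In YAP and SRF targets 6 of 15 rose, 2 fell and 7 did not pass (7 and 2 adjusted over the list alone, camera adjusted p = 0.0401, adjusted p = 0.446 with an estimated correlation, adjusted p = 0.0596 with the replicate block). The actin-binding TPM1 rose from 292 ± 21 to 1270 ± 38 CPM. In DNA methylation machinery 2 of 7 rose and 5 did not pass (4 adjusted over the list alone, camera adjusted p = 0.0432, adjusted p = 0.348 with an estimated correlation, adjusted p = 0.0596 with the replicate block). The demethylase TET3 rose from 40.3 ± 10 to 89.3 ± 3.2 CPM. Over all genes 3876 rose and 4400 fell by edgeR, 2142 and 2764 by at least 2-fold, and 8212 of the 8276 moved in the same direction in all 3 same-numbered pairs.

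From day 2 to day 4 the surface ectoderm list tested higher again. DLX5 (ENSG00000105880, chromosome 7, 97020392 to 97024950) rose from 3.79 ± 0.44 to 63.2 ± 23 CPM (log2 fold change 4.06, SE 0.27, adjusted p = 5.38e-08). Of its list 5 of 11 rose and 6 did not pass (6 adjusted over the list alone, camera adjusted p = 4.73e-07, adjusted p = 0.297 with an estimated correlation). DLX3 rose from 1.57 ± 0.14 to 14.1 ± 4.3 and DLX6 from 0.985 ± 0.23 to 8.95 ± 3.8 CPM. GATA3 rose from 3.31 ± 0.45 to 37.6 ± 18 CPM. Of the amnion and trophoblast genes, 6 of 16 rose and 10 did not pass (11 adjusted over the list alone, camera adjusted p = 1.46e-05, adjusted p = 0.452 with an estimated correlation). TBX3 rose from 2.62 ± 0.55 to 9.97 ± 4.2 and the GABA receptor subunit GABRP from 0.734 ± 0.22 to 3.44 ± 2.6 CPM. Of the BMP targets, 5 of 13 rose and 8 did not pass (7 adjusted over the list alone, camera adjusted p = 0.000173, adjusted p = 0.297 with an estimated correlation). MSX2 rose from 4.48 ± 0.59 to 20.4 ± 8.4 and SMAD6 from 15.8 ± 2.8 to 36.8 ± 10 CPM. Of the paraxial mesoderm and somite genes, 3 of 12 rose and 9 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.0179, adjusted p = 0.434 with an estimated correlation). FOXC1 rose from 0.944 ± 0.054 to 7.65 ± 2.2 and the Notch ligand DLL1 from 6.91 ± 2.2 to 25.4 ± 11 CPM. DLK1, a paternally expressed imprinted gene, rose from 2.13 ± 0.83 to 72.8 ± 19 and the maternally expressed MEG3 from 0.276 ± 0.2 to 6.53 ± 0.22 CPM. Of the imprinted list 2 of 14 rose and 12 did not pass (2 and 1 adjusted over the list alone, camera adjusted p = 0.0454, adjusted p = 0.297 with an estimated correlation), a call lost with the replicate block (adjusted p = 0.0604). MT1E and MT1G were higher again, at 0.665 ± 0.26 and then 13.8 ± 12 and at 0.89 ± 0.042 and then 16 ± 15 CPM, and BAHCC1 rose from 1.09 ± 0.39 to 15.1 ± 8 CPM.

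Among the largest falls were those of POU3F4, from 6.64 ± 2 to 0.355 ± 0.1, and OLIG3, from 10.5 ± 2.5 to 0.897 ± 0.41 CPM. ETS1 fell from 53.2 ± 16 to 7.93 ± 0.56, PDZD4 from 27 ± 4 to 4.04 ± 0.78 and HHIP from 22.5 ± 6 to 3.66 ± 0.76 CPM. In primed pluripotency 0 of 22 fell and 22 did not pass (0 adjusted over the list alone, camera adjusted p = 0.000704, adjusted p = 0.618 with an estimated correlation). TDGF1, a NODAL co-receptor, measured 418 ± 78 and then 98.5 ± 8 CPM (adjusted p = 0.16). In cell cycle 1 of 20 fell and 19 did not pass (2 adjusted over the list alone, camera adjusted p = 0.000173, adjusted p = 0.527 with an estimated correlation). The ribonucleotide reductase subunit RRM2 fell from 267 ± 50 to 134 ± 22 CPM. In NODAL and activin targets 2 of 10 fell, 1 rose and 7 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.0366, adjusted p = 0.482 with an estimated correlation), a call lost with the replicate block (adjusted p = 0.0558). SKIL fell from 274 ± 67 to 117 ± 4.7 CPM. The stress response list was lower (camera adjusted p = 0.0219, adjusted p = 0.527 with an estimated correlation), and in it VLDLR fell from 21 ± 1.4 to 12.2 ± 0.72 CPM. With 0 members passing, cholesterol synthesis was lower too (camera adjusted p = 0.00365, adjusted p = 0.618 with an estimated correlation). So were mitochondrially encoded genes (camera adjusted p = 0.00432, adjusted p = 0.618 with an estimated correlation) and histones (camera adjusted p = 0.000173, adjusted p = 0.527 with an estimated correlation). The heat shock list, not called here (adjusted p = 0.071), was lower with the block (adjusted p = 0.0433).

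By edgeR, 602 genes rose and 319 fell from day 2 to day 4, 437 and 171 by at least 2-fold. All 921 moved in the same direction in the 3 same-numbered pairs, which their selection nearly assured. With the replicate block 1332 rose and 908 fell. The lowest counts with a library left out were 194 higher without EB day 2 replicate 1 and 99 lower without EB day 4 replicate 2.

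From day 4 to day 6 HOX genes of the anterior paralog groups, which pattern the hindbrain and neck, rose. HOXB1 rose from 0.0674 ± 0.063 to 2.07 ± 1.1 CPM (log2 fold change 4.88, SE 0.95, adjusted p = 0.00236). HOXB2 rose from 0.0883 ± 0.095 to 1.16 ± 0.53 and HOXA2 from 0.0436 ± 0.017 to 0.615 ± 0.15 CPM, but with the Salmon estimates HOXA2 did not pass (log2 fold change 1.69 against 3.68, adjusted p = 0.543). Of the list 5 of 7 rose and 2 did not pass (5 adjusted over the list alone, camera adjusted p = 8.79e-06, adjusted p = 0.19 with an estimated correlation). HOX genes overlap antisense transcripts, so part of their counts is uncertain. Retinoic acid response genes tested higher too: 8 of 16 rose, 1 fell and 7 did not pass (8 and 1 adjusted over the list alone, camera adjusted p = 1.34e-05, adjusted p = 0.0538 with an estimated correlation). The nuclear receptor NR2F2 rose from 1.68 ± 0.48 to 36.4 ± 5.9 and MEIS1 from 4.21 ± 3.1 to 50.6 ± 19 CPM. MEIS2 rose from 40 ± 2.2 to 139 ± 29 CPM. Of amnion and trophoblast genes 11 of 16 rose and 5 did not pass (13 adjusted over the list alone, camera adjusted p = 1.35e-09, adjusted p = 0.108 with an estimated correlation). GABRP rose from 3.44 ± 2.6 to 44.9 ± 17 and WNT6 from 0.692 ± 0.51 to 9.07 ± 2.3 CPM. In surface ectoderm 8 of 11 rose and 3 did not pass (11 adjusted over the list alone, camera adjusted p = 6.47e-10, adjusted p = 0.0538 with an estimated correlation). TP63, a regulator of stratified epithelium, rose from 0.111 ± 0.08 to 3.55 ± 1.7 and DLX3 from 14.1 ± 4.3 to 62.6 ± 13 CPM. In the epithelial list 7 of 14 rose and 7 did not pass (7 adjusted over the list alone, camera adjusted p = 4.70e-06, adjusted p = 0.17 with an estimated correlation). The keratin KRT8 rose from 558 ± 110 to 2350 ± 420 and KRT18 from 107 ± 16 to 405 ± 47 CPM.

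Lists of mesodermal and mesenchymal genes tested higher over the same interval. In mesenchyme and extracellular matrix 10 of 20 rose and 10 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 0.00123, adjusted p = 0.108 with an estimated correlation). The receptor PDGFRA rose from 4.18 ± 0.22 to 18.2 ± 1.9 and the proteoglycan LUM from 0.285 ± 0.46 to 11.2 ± 5 CPM. The collagen COL3A1 rose from 0.0493 ± 0.085 to 4.09 ± 3.6 CPM. In lateral and cardiac mesoderm 6 of 12 rose and 6 did not pass (9 adjusted over the list alone, camera adjusted p = 2.33e-06, adjusted p = 0.0911 with an estimated correlation). ISL1 rose from 13.4 ± 4.3 to 69.7 ± 19 and HAND1 from 9.25 ± 3.4 to 35.4 ± 7.2 CPM. In paraxial mesoderm and somite 4 of 12 rose, 1 fell and 7 did not pass (4 and 1 adjusted over the list alone, camera adjusted p = 0.0324, adjusted p = 0.228 with an estimated correlation), a call lost with the replicate block (adjusted p = 0.0706). FOXC1 rose from 7.65 ± 2.2 to 67.7 ± 6.8 and FOXC2 from 0.529 ± 0.073 to 15.2 ± 4.3 CPM. In BMP targets 8 of 13 rose and 5 did not pass (9 adjusted over the list alone, camera adjusted p = 1.52e-06, adjusted p = 0.089 with an estimated correlation). MSX1 rose from 0.406 ± 0.074 to 3.72 ± 0.95 CPM. In WNT targets 5 of 14 rose and 9 did not pass (7 and 2 adjusted over the list alone, camera adjusted p = 0.0079, adjusted p = 0.139 with an estimated correlation). The WNT inhibitor DKK1 rose from 0.404 ± 0.023 to 10.7 ± 9.8 and LGR5 from 0.107 ± 0.043 to 1.28 ± 0.43 CPM. In definitive endoderm 3 of 9 rose and 6 did not pass (3 and 1 adjusted over the list alone, camera adjusted p = 0.0183, adjusted p = 0.141 with an estimated correlation). GATA6, also a mesoderm factor, rose from 0.379 ± 0.1 to 3.13 ± 1.1 and SHISA2 from 179 ± 9.8 to 498 ± 150 CPM. SLITRK6, a neuronal membrane protein, rose from 0.194 ± 0.099 to 10.1 ± 0.57 CPM.

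Of the primed pluripotency genes, 6 of 22 fell and 16 did not pass (14 adjusted over the list alone, camera adjusted p = 4.70e-06, adjusted p = 0.467 with an estimated correlation). The surface sialomucin PODXL fell from 1880 ± 150 to 1120 ± 73 and the growth factor FGF2 from 103 ± 3.2 to 46.6 ± 4.4 CPM. DPPA4 fell from 462 ± 67 to 225 ± 24 CPM. Cholesterol synthesis tested lower with 0 of 21 members passing (camera adjusted p = 0.0141, adjusted p = 0.668 with an estimated correlation). The cell cycle and heat shock lists, not called here (adjusted p = 0.0522 and 0.0556), were lower with the replicate block (adjusted p = 0.022 and 0.0266). IDO1, which degrades tryptophan, fell from 54.4 ± 18 to 4.27 ± 1.6 and the adrenergic receptor ADRA2A from 15.6 ± 5 to 1.64 ± 0.66 CPM. FGF19 fell from 5.96 ± 1 to 1.03 ± 0.48 and SLC24A2 from 11.5 ± 3.8 to 1.74 ± 0.68 CPM. The calcium channel CACNA1E fell from 11.6 ± 2.6 to 2.04 ± 0.27 CPM. In all, 1435 genes rose and 792 fell, 990 and 525 by at least 2-fold. Of the 2227, 2223 moved in the same direction in the 3 same-numbered pairs, which their selection nearly assured. With the replicate block 1376 fell, and without EB day 6 replicate 2 the counts were 849 and 264.

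The interval from day 6 to day 8 held the fewest calls of the 7 comparisons. VIM, the intermediate filament of mesenchymal cells, rose from 15.9 ± 3.4 to 53.8 ± 11 CPM (log2 fold change 1.76, SE 0.22, adjusted p = 0.000711). Of the mesenchyme and extracellular matrix list 1 of 20 rose and 19 did not pass (10 and 2 adjusted over the list alone, camera adjusted p = 4.09e-05, adjusted p = 0.0782 with an estimated correlation). CDH11 (ENSG00000140937, chromosome 16, 64943753 to 65126112), a mesenchymal cadherin, rose from 7.68 ± 1.5 to 46.1 ± 31, the matrix protein SMOC1 from 3.51 ± 1.3 to 27.1 ± 15, WNT5B from 0.873 ± 0.33 to 8.49 ± 6.8, the nuclear receptor RORB from 0.575 ± 0.23 to 5.57 ± 4.7 and SLITRK1 from 0.122 ± 0.04 to 8.29 ± 10 CPM. Of the FGF and ERK targets, 2 of 14 rose and 12 did not pass (4 adjusted over the list alone, camera adjusted p = 0.000132, adjusted p = 0.212 with an estimated correlation). DUSP6 rose from 1.69 ± 0.32 to 9.81 ± 5.4 and SPRY2 from 25.7 ± 3.6 to 44.5 ± 8 CPM. FAS, the death receptor, rose from 1.75 ± 0.33 to 4.4 ± 1 CPM in the p53 target list, where 1 of 16 rose and 15 did not pass (1 adjusted over the list alone, camera adjusted p = 0.01, adjusted p = 0.561 with an estimated correlation). EDN1 fell from 71.8 ± 1.5 to 27.4 ± 7.4 and the FGF receptor FGFR3 from 161 ± 13 to 71.1 ± 11 CPM. SOX15 fell from 30.8 ± 10 to 13.7 ± 1.3 and OPCML from 22.4 ± 1.5 to 10 ± 0.83 CPM. CBLC fell from 11.6 ± 1.3 to 5.38 ± 0.75 CPM.

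Neuroectoderm tested higher with 0 of 16 members passing and 5 higher adjusted over the list alone (camera adjusted p = 0.000132, adjusted p = 0.452 with an estimated correlation). Its gene LHX2 measured 2.12 ± 1.1 and then 34 ± 39 CPM (adjusted p = 0.152, 0.0497 with the replicate block) and RAX 4.12 ± 3.3 and then 33.6 ± 40 CPM. Replicate 1 held most of these transcripts at day 8, with SOX2 at 691 CPM against 225 and 119 and PAX6 at 124 against 53.6 and 23.4. In imprinted genes 0 of 14 rose and 14 did not pass (3 adjusted over the list alone, camera adjusted p = 0.00486, adjusted p = 0.0782 with an estimated correlation). IGF2 measured 3.62 ± 2.1 and then 22.5 ± 23 CPM (adjusted p = 0.054, 0.0067 with the replicate block). In the epithelial list 0 of 14 fell and 14 did not pass (5 adjusted over the list alone, camera adjusted p = 4.27e-09, adjusted p = 0.109 with an estimated correlation). The adhesion molecule EPCAM measured 173 ± 15 and then 124 ± 23 CPM (adjusted p = 0.237). Higher too, with 0 members passing, were neuron (camera adjusted p = 0.00475, adjusted p = 0.217 with an estimated correlation) and anterior HOX (camera adjusted p = 0.0086, adjusted p = 0.546 with an estimated correlation). The same held for NODAL and activin targets (camera adjusted p = 0.00951, adjusted p = 0.212 with an estimated correlation) and mitochondrially encoded genes (camera adjusted p = 0.00425, adjusted p = 0.675 with an estimated correlation). Surface ectoderm (camera adjusted p = 0.00103, adjusted p = 0.217 with an estimated correlation) and BMP targets (camera adjusted p = 0.0013, adjusted p = 0.212 with an estimated correlation) were lower. YAP and SRF targets (camera adjusted p = 0.000161, adjusted p = 0.212 with an estimated correlation), naive pluripotency (camera adjusted p = 0.00749, adjusted p = 0.109 with an estimated correlation) and primordial germ cell (camera adjusted p = 0.0106, adjusted p = 0.212 with an estimated correlation) were also lower. Among the members of these 5 lists SOX15 alone passed.

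By edgeR 70 genes rose and 16 fell from day 6 to day 8, 63 and 11 by at least 2-fold. All 86 moved in the same direction in the 3 same-numbered pairs, which their selection nearly assured. With the replicate block 184 rose and 75 fell. A fit of these 6 libraries alone called 0 genes by edgeR (628 higher and 541 lower at an unadjusted p under 0.05), while DESeq2 on all libraries called 204 and 90. The lowest counts with a library left out were 16 higher without EB day 6 replicate 2 and 1 lower without EB day 6 replicate 1. Without EB day 8 replicate 1, 7 of the 15 list calls of this interval remained.

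From day 8 to day 10 genes of placental and amniotic tissue and of extracellular matrix rose. CGA (ENSG00000135346, chromosome 6, 87085498 to 87095406), the alpha subunit of chorionic gonadotropin, rose from 13.3 ± 2.7 to 247 ± 72 CPM (log2 fold change 4.21, SE 0.39, adjusted p = 3.05e-06). HSD3B1, an enzyme of placental steroid synthesis with a close paralog, rose from 0.49 ± 0.22 to 12.9 ± 5.7, and LGALS16, a placental galectin of a paralogous cluster, from 0.313 ± 0.098 to 5.54 ± 2 CPM. Of the amnion and trophoblast list, 11 of 16 rose and 5 did not pass (11 adjusted over the list alone, camera adjusted p = 2.95e-10, adjusted p = 0.106 with an estimated correlation). ERVW-1, which encodes the fusion protein syncytin 1, rose from 3.94 ± 1.7 to 46.6 ± 14 and HAND1 from 37.7 ± 23 to 270 ± 95 CPM. CGB5, one of a group of near-identical paralogs, rose from 0.0896 ± 0.032 to 2.05 ± 0.55 CPM. Of the mesenchyme and extracellular matrix list, 12 of 20 rose, 1 fell and 7 did not pass (12 and 1 adjusted over the list alone, camera adjusted p = 3.72e-08, adjusted p = 0.0187 with an estimated correlation). SPARC rose from 109 ± 0.9 to 275 ± 55 and VIM from 53.8 ± 11 to 198 ± 43 CPM. The proteoglycan DCN rose from 4.46 ± 3.1 to 68.8 ± 35 and smooth muscle actin ACTA2 from 2.13 ± 0.27 to 13.2 ± 6.5 CPM. The phosphatase PHOSPHO1 rose from 0.337 ± 0.27 to 6.84 ± 1.7 and the hormone SST from 1.09 ± 0.86 to 19.3 ± 12 CPM.

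Of cardiac sarcomere genes 10 of 14 rose and 4 did not pass (11 and 1 adjusted over the list alone, camera adjusted p = 3.40e-07, adjusted p = 0.106 with an estimated correlation). The calcium release channel RYR2 rose from 35.6 ± 13 to 118 ± 29 and troponin TNNT2 from 5.33 ± 3.1 to 22.6 ± 5.9 CPM. MYL7 rose from 0.265 ± 0.096 to 2.12 ± 0.99 CPM. In lateral and cardiac mesoderm 7 of 12 rose, 1 fell and 4 did not pass (7 and 1 adjusted over the list alone, camera adjusted p = 0.00415, adjusted p = 0.21 with an estimated correlation). GATA6 rose from 5.77 ± 5.5 to 32.1 ± 15 and HAND2 from 1.25 ± 1.4 to 8.79 ± 2.8 CPM. In anterior HOX genes 7 of 7 rose (7 adjusted over the list alone, camera adjusted p = 8.61e-07, adjusted p = 0.153 with an estimated correlation). HOXB1 rose from 6.48 ± 6.3 to 77.8 ± 42 and HOXB2 from 4.37 ± 4 to 28.5 ± 12 CPM. HOXB3 rose from 2.45 ± 2.5 to 15 ± 6.5 CPM. In the retinoic acid list 9 of 16 rose, 2 fell and 5 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.0055, adjusted p = 0.133 with an estimated correlation). The retinoic acid-degrading enzyme CYP26A1 fell from 47.5 ± 11 to 8.7 ± 9.4 CPM. In immediate early genes 7 of 13 rose and 6 did not pass (7 adjusted over the list alone, camera adjusted p = 0.000192, adjusted p = 0.153 with an estimated correlation). JUN rose from 22.2 ± 5.5 to 65.8 ± 9.8 CPM. In the stress response list 6 of 16 rose and 10 did not pass (8 and 3 adjusted over the list alone, camera adjusted p = 0.00833, adjusted p = 0.237 with an estimated correlation). HERPUD1 rose from 34.9 ± 15 to 113 ± 41 and the chaperone HSPA5 from 291 ± 47 to 497 ± 37 CPM. Higher too were YAP and SRF targets, with 6 of 15 rising (camera adjusted p = 0.000569, adjusted p = 0.168 with an estimated correlation), and BMP targets, with 4 of 13 (camera adjusted p = 0.00731, adjusted p = 0.226 with an estimated correlation). In epithelial genes 4 of 14 rose (camera adjusted p = 0.00174, adjusted p = 0.26 with an estimated correlation), and in visceral endoderm genes 4 of 11 (camera adjusted p = 0.0153, adjusted p = 0.106 with an estimated correlation). The apolipoprotein APOB rose from 4.73 ± 1.3 to 13 ± 4.3 CPM.

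The neuroectoderm, primed pluripotency and somite lists tested lower over the last interval. In neuroectoderm 3 of 16 fell and 13 did not pass (4 adjusted over the list alone, camera adjusted p = 3.33e-05, adjusted p = 0.26 with an estimated correlation). OTX1 fell from 34.2 ± 7.3 to 10 ± 8.3 and OTX2 from 183 ± 80 to 55.3 ± 58 CPM. SIX3 fell from 75.4 ± 60 to 11.2 ± 17 CPM. In primed pluripotency 3 of 22 fell and 19 did not pass (4 adjusted over the list alone, camera adjusted p = 6.68e-07, adjusted p = 0.296 with an estimated correlation). TRIM71 fell from 791 ± 150 to 439 ± 160 and LIN28A from 1710 ± 370 to 920 ± 480 CPM. At day 10 the replicates differed in these genes, with POU5F1 at 245 CPM in replicate 1 against 18 and 51.4, SOX2 at 277 against 15.4 and 33.3, and PAX6 at 68.9 against 0.888 and 3.74. In paraxial mesoderm and somite 6 of 12 fell and 6 did not pass (7 adjusted over the list alone, camera adjusted p = 0.000569, adjusted p = 0.106 with an estimated correlation). FOXC1 fell from 49.7 ± 11 to 11.8 ± 6.2 and FOXC2 from 9.77 ± 5.4 to 0.928 ± 1.1 CPM. PAX3 fell from 5.69 ± 1.7 to 1.67 ± 0.76 CPM. In Notch targets 3 of 12 fell and 9 did not pass (5 adjusted over the list alone, camera adjusted p = 0.00512, adjusted p = 0.226 with an estimated correlation). HEYL fell from 2.81 ± 0.94 to 0.745 ± 0.58 CPM. In definitive endoderm 3 of 9 fell, 1 rose and 5 did not pass (6 and 1 adjusted over the list alone, camera adjusted p = 0.00591, adjusted p = 0.116 with an estimated correlation). SHISA2 fell from 302 ± 59 to 93.1 ± 27 and PRDM1 from 41.7 ± 12 to 8.85 ± 4.5 CPM, while GATA6 rose. Lower with 2 and 1 members falling were primordial germ cell (camera adjusted p = 0.0153, adjusted p = 0.168 with an estimated correlation) and primitive streak (camera adjusted p = 0.0197, adjusted p = 0.196 with an estimated correlation). Cell cycle had 1 member falling (camera adjusted p = 0.000587, adjusted p = 0.419 with an estimated correlation) and cholesterol synthesis 0 (camera adjusted p = 0.0325, adjusted p = 0.716 with an estimated correlation).

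CYP26C1, another retinoic acid hydroxylase, fell from 69.3 ± 27 to 6.29 ± 8.3 and PAQR9 from 23.4 ± 9.3 to 2.46 ± 2.7 CPM. LHX5 fell from 48.5 ± 26 to 7.12 ± 10 CPM. ARHGEF39 was lower at day 10, at 113 ± 170 and then 12.5 ± 1.9 CPM, but EB day 8 replicate 2 alone held 306 CPM against 19.1 and 15.5. The deposited Salmon estimates gave 17.3, 15.4 and 16.3 CPM for the same libraries. Between day 8 and day 10, 2013 genes rose and 1138 fell by edgeR, 1445 and 634 by at least 2-fold. The counts were 1032 and 244 without EB day 10 replicate 2, and 2825 and 3008 without EB day 10 replicate 1. A fit of these 6 libraries alone called 226 and 11 genes, and without all replicate 1 libraries 3131 rose and 3075 fell.

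**Figure D3:**
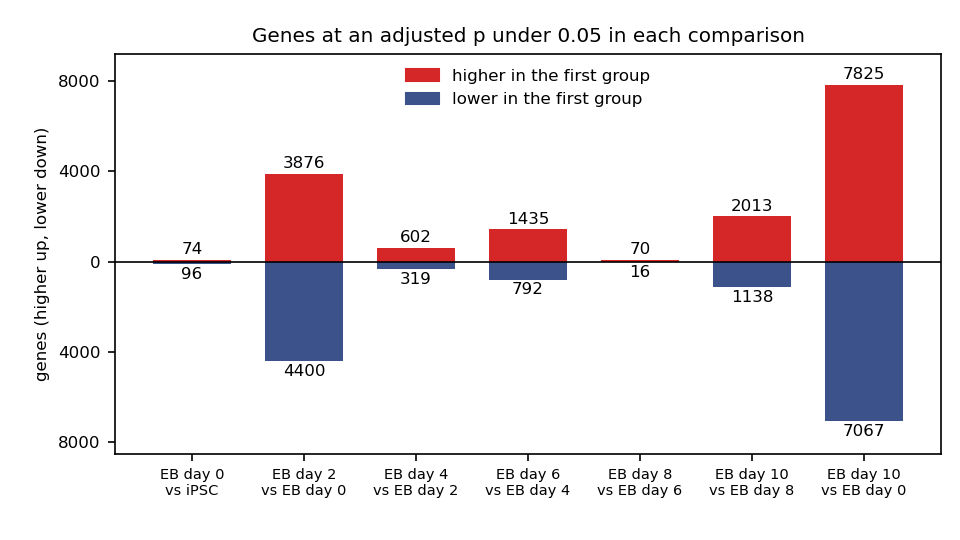
Bars give the number of genes called higher and lower by edgeR in each of the 7 comparisons. The counts run from 86 genes for EB day 8 against day 6 to 14892 for EB day 10 against day 0.

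From day 0 to day 10, genes of amnion, trophoblast, surface ectoderm and mesenchyme rose and genes of primed pluripotency fell. HAND1 (ENSG00000113196, chromosome 5, 154474972 to 154478264) rose from 0.16 ± 0.023 to 270 ± 95 CPM (log2 fold change 10.67, SE 0.60, adjusted p = 6.90e-11). CGA rose from 0.0877 ± 0.095 to 247 ± 72, TFAP2A from 0.0848 ± 0.052 to 125 ± 17, VTCN1, an immune checkpoint ligand of trophoblast and amnion, from 0.365 ± 0.18 to 519 ± 220, and COL3A1 from 0.138 ± 0.043 to 457 ± 250 CPM. Some genes had almost no counts at day 0. LUM reached 357 ± 190 CPM against 2 counts, a ratio of 13500 (95% interval 3740 to 112000), and the integrin ITGB6 126 ± 65 against 2 counts, a ratio of 4760 (1320 to 39300). TFAP2B reached 97 ± 35 against 3 counts, a ratio of 2420 (827 to 11700), and GATA6 32.1 ± 15 against 1 count, a ratio of 2410 (432 to 95100). CYSLTR2, a leukotriene receptor, was at least 159-fold higher at 6.47 ± 1 CPM against 0 counts.

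Of the amnion and trophoblast list 16 of 16 rose (16 adjusted over the list alone, camera adjusted p = 2.61e-12, adjusted p = 0.0585 with an estimated correlation). Of surface ectoderm 11 of 11 rose (11 adjusted over the list alone, camera adjusted p = 5.19e-08, adjusted p = 0.0585 with an estimated correlation). DLX5 rose from 0.057 ± 0.05 to 32.8 ± 6.3 and DLX3 from 0.265 ± 0.066 to 29 ± 0.92 CPM. GATA3 rose from 0.157 ± 0.065 to 191 ± 36 CPM. In BMP targets 12 of 13 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 5.19e-08, adjusted p = 0.0585 with an estimated correlation). MSX2 rose from 0.175 ± 0.093 to 94.2 ± 16 and ID4 from 6.1 ± 1.5 to 78.3 ± 17 CPM. In the retinoic acid list 11 of 16 rose and 5 did not pass (11 adjusted over the list alone, camera adjusted p = 9.24e-05, adjusted p = 0.0585 with an estimated correlation). MEIS2 rose from 0.5 ± 0.19 to 226 ± 46 and NR2F2 from 0.223 ± 0.094 to 149 ± 43 CPM. MEIS1 rose from 0.513 ± 0.33 to 283 ± 88 CPM. In lateral and cardiac mesoderm 10 of 12 rose, 1 fell and 1 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 1.05e-05, adjusted p = 0.0825 with an estimated correlation). ISL1 rose from 0.691 ± 0.25 to 78 ± 6.9 and TBX3 from 0.505 ± 0.3 to 153 ± 43 CPM. In cardiac sarcomere 13 of 14 rose and 1 fell (13 and 1 adjusted over the list alone, camera adjusted p = 9.24e-05, adjusted p = 0.14 with an estimated correlation). RYR2 rose from 15.1 ± 2.3 to 118 ± 29 and the heavy chain MYH6 from 0.24 ± 0.091 to 4.7 ± 0.3 CPM. In mesenchyme and extracellular matrix 14 of 20 rose, 3 fell and 3 did not pass (14 and 3 adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.11 with an estimated correlation). DCN rose from 0.182 ± 0.1 to 68.8 ± 35 and COL5A1 from 7.27 ± 3.1 to 148 ± 46 CPM. In imprinted genes 10 of 14 rose, 1 fell and 3 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.0643 with an estimated correlation). The growth inhibitor CDKN1C rose from 10.5 ± 0.85 to 98.3 ± 21 and its neighbour H19 from 1.98 ± 0.71 to 281 ± 100 CPM. IGF2 rose from 0.29 ± 0.094 to 164 ± 57 CPM. In anterior HOX genes 7 of 7 rose (7 adjusted over the list alone, camera adjusted p = 7.54e-05, adjusted p = 0.273 with an estimated correlation). HOXB1 rose from 0.0877 ± 0.095 to 77.8 ± 42 CPM. In YAP and SRF targets 10 of 15 rose, 3 fell and 2 did not pass (10 and 3 adjusted over the list alone, camera adjusted p = 0.0269, adjusted p = 0.371 with an estimated correlation). ANKRD1 rose from 0.122 ± 0.076 to 20.4 ± 5.6 CPM. The no-feature share was also higher at day 10, at 43.24% ± 4.29 against 20.92% ± 1.72 at day 0.

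Of the primed pluripotency genes 21 of 22 fell and 1 did not pass (21 adjusted over the list alone, camera adjusted p = 1.09e-07, adjusted p = 0.342 with an estimated correlation). DPPA4 fell from 852 ± 110 to 155 ± 98 and L1TD1 from 1450 ± 280 to 354 ± 140 CPM. FOXD3 fell from 10.5 ± 0.65 to 0.258 ± 0.27 CPM. In hypoxia and glycolysis 17 of 20 fell, 1 rose and 2 did not pass (17 and 1 adjusted over the list alone, camera adjusted p = 5.19e-08, adjusted p = 0.0585 with an estimated correlation). The glycolytic enzyme LDHA fell from 2010 ± 21 to 74.1 ± 22 and PGK1 from 1990 ± 230 to 137 ± 28 CPM. In cholesterol synthesis 20 of 21 fell and 1 did not pass (20 adjusted over the list alone, camera adjusted p = 5.07e-07, adjusted p = 0.329 with an estimated correlation). MVD fell from 48.1 ± 5.5 to 11.4 ± 3 CPM. In neuron 7 of 11 fell and 4 did not pass (7 adjusted over the list alone, camera adjusted p = 0.00703, adjusted p = 0.273 with an estimated correlation). TUBB3 fell from 157 ± 26 to 13.4 ± 6.6 CPM. In FGF and ERK targets 9 of 14 fell, 2 rose and 3 did not pass (9 and 2 adjusted over the list alone, camera adjusted p = 0.00933, adjusted p = 0.371 with an estimated correlation). SPRY4 fell from 300 ± 73 to 18.6 ± 9.5 CPM. In cell cycle 12 of 20 fell, 1 rose and 7 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 0.0027, adjusted p = 0.531 with an estimated correlation). The replication licensing factor MCM3 fell from 602 ± 86 to 226 ± 86 CPM. Both markers of RNA quality were lower. In mitochondrially encoded genes 12 of 13 fell and 1 did not pass (13 adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.531 with an estimated correlation). In histones 13 of 15 fell and 2 did not pass (14 adjusted over the list alone, camera adjusted p = 0.00191, adjusted p = 0.531 with an estimated correlation).

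Among the named genes the largest falls were those of the metallothioneins MT1G, from 440 ± 180 to 1.25 ± 0.51, and MT1H, from 103 ± 48 to 0.334 ± 0.18 CPM. MT1M fell to 3 counts, a ratio of 199 (67.7 to 968). ONECUT1 fell from 47.7 ± 21 to 0.265 ± 0.066 and the kinase LCK from 148 ± 21 to 0.98 ± 1.4 CPM. The neuronal pentraxin NPTX1 fell from 38.2 ± 15 to 0.273 ± 0.061 and the secretory granule protein CHGA from 103 ± 22 to 0.92 ± 0.89 CPM. The peptide hormone APLN fell from 8.55 ± 4.9 to 0.102 ± 0.15 and TMEM26 from 5.2 ± 0.83 to 0.0696 ± 0.06 CPM. SEMG1 fell from 5.07 ± 1.3 to 0.068 ± 0.089 CPM. In this comparison 7825 genes rose and 7067 fell by edgeR, 5863 and 4580 by at least 2-fold. With the replicate block and the no-feature share of each library as a covariate, 4075 rose and 3636 fell.

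The profile genes traced the course. POU5F1, the core pluripotency factor, measured 1170 ± 82 CPM in iPSCs, 1350 ± 69 at day 0, 836 ± 95, 484 ± 15, 184 ± 8.1 and 173 ± 96 at days 2 to 8, and 105 ± 120 at day 10 (day 10 against day 0, adjusted p = 4.04e-05). NANOG fell from 112 ± 12 to 7.36 ± 9.9 at day 10 and SOX2 from 575 ± 71 to 109 ± 150 CPM. DNMT3B, the de novo DNA methyltransferase, was highest at day 2, at 3320 ± 130, and fell from 1920 ± 380 to 465 ± 490 CPM over the course. PAX6 was highest at day 8, at 66.9 ± 51, and AFP, an early liver and yolk sac product, fell from 4.31 ± 2.5 to 0.214 ± 0.077 CPM. The profile genes TBXT, EOMES, MIXL1, SOX17 and FOXA2, markers of primitive streak and endoderm, had means under 2 CPM in every group. TBXT was highest at 0.279 ± 0.18 CPM on day 4, EOMES at 1.89 ± 0.4 on day 2 and MIXL1 at 1.24 ± 0.17 in iPSCs. SOX17 and FOXA2 had too few counts to be tested, at most 5 and 15 counts in the 3 libraries of a group.

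**Figure D4:**
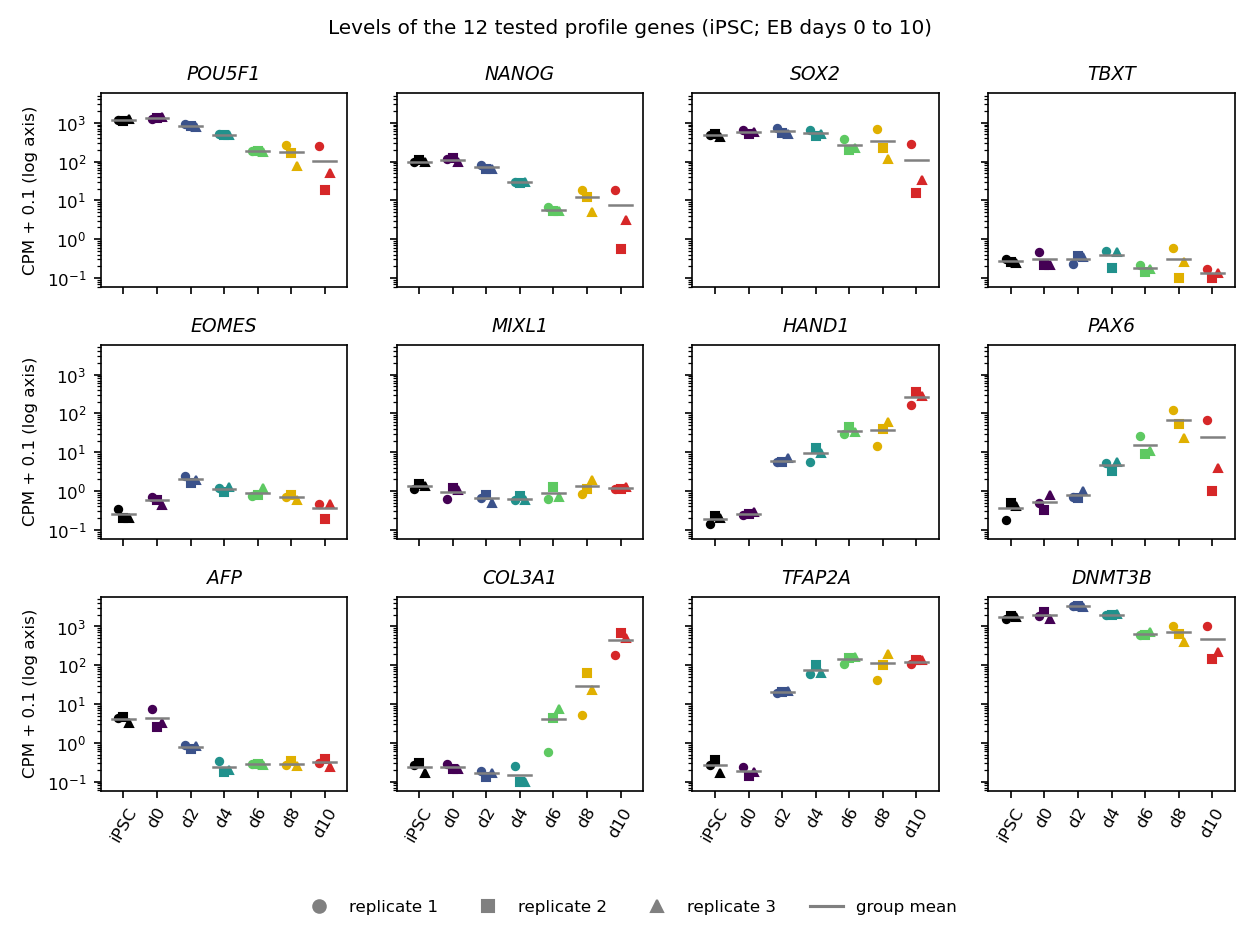
The 12 profile genes that could be tested are plotted by group on a log axis of CPM plus 0.1, with points for the 3 replicates and bars at the group means. POU5F1 runs from 1350 CPM at EB day 0 to 105 at day 10 while HAND1 runs from 0.16 to 270.

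Over the EB time course, 17052 of the 24301 genes changed in a joint edgeR test of days 2 to 10 against day 0. Of these genes, 907 peaked between and lay at least 2-fold above both ends, 176 at day 2, 420 at day 4, 226 at day 6 and 85 at day 8. At day 2 the peak genes included ADRA2A, at 68.1 ± 4.3 CPM against 4.17 ± 0.51 at day 0 and 2.19 ± 1.9 at day 10, and PTCH1, at 660 ± 2.3 against 50.2 ± 12 and 86 ± 52. The growth factor FGF4 lay at 19.1 ± 1.2 against 1.44 ± 0.76 and 2.5 ± 3.2, HTR1D at 38.1 ± 2.1 against 3.99 ± 1.2 and 2.67 ± 2.9 and PCDH8 at 37 ± 5.3 against 0.733 ± 0.22 and 4.73 ± 1.2. LHX5 and SIX3 peaked at day 4, LHX5 at 155 ± 12 against 0.369 ± 0.064 and 7.12 ± 10, and SIX3 at 103 ± 5.3 against 0.121 ± 0.14 and 11.2 ± 17. CYP26A1 peaked with them, at 157 ± 38 against 1.67 ± 0.34 and 8.7 ± 9.4, LMO1, at 18.2 ± 4.2, and the germ cell gene DAZL, at 9.45 ± 3.3 CPM.

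Genes peaking at day 6 included FOXC2, at 15.2 ± 4.3 against 0.0921 ± 0.087 at day 0 and 0.928 ± 1.1 at day 10, and DKK1, at 10.7 ± 9.8 against 0.434 ± 0.045 and 0.705 ± 0.65. CYP26C1 lay at 76.4 ± 3.1 against 0.295 ± 0.072 and 6.29 ± 8.3 and the guidance cue SEMA3E at 123 ± 24 against 11.1 ± 1.5 and 12.1 ± 9.1 CPM. SLC5A10 was also called, but its day 6 libraries held 1.63, 0.769 and 348 CPM and the Salmon estimates gave at most 0.18 CPM there. Those peaking at day 8 included PAQR9, at 23.4 ± 9.3 against 2.53 ± 0.34 and 2.46 ± 2.7, and the cortical factor FEZF2, at 6.63 ± 2.6. The sodium channel SCN7A lay at 28.2 ± 15 and PAX7 at 13.6 ± 6.4 against 0.412 ± 0.093 and 2.67 ± 4.1 CPM. Without all replicate 1 libraries the numbers were 268, 690 and 221 at days 2, 4 and 8. With EB day 10 replicate 2 left out, 26 genes peaked at day 8, and with EB day 10 replicate 1 left out 184 did.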

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

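Of the tests in this part, those of slower progress at days 2, 4 and 10 alone, of the lower no-feature share of replicate 1, of SLC30A1, of olfactory receptor and sense intronic genes and of the covariate fit were chosen only after the result was seen. The share of reads assigned to no annotated feature was tested in no comparison of the report. It was higher in every EB group from day 2 on than in the undifferentiated controls. Its mean was 31.85% at day 2, 38.03% at day 4, 37.56% at day 6, 40.59% at day 8 and 43.24% at day 10, against 19.92% ± 1.48 in iPSCs (n = 3). No sample was tested as an outlier, since the groups have 3 libraries, and no test of a difference between 2 groups' effects was made.

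The first pattern is the distance of the replicate 1 libraries from replicates 2 and 3 at days 2 to 10, and slower progress of replicate 1 at every day would need its difference from another replicate to correlate negatively across genes with the change of the remaining one since the day before. The highest of 10 such correlations was 0.022, with 0.021 at day 6 and 0.022 at day 8 against the change of replicate 2, but -0.255 and -0.218 against that of replicate 3, so slower progress over the whole course stays open. At days 2, 4 and 10 the highest of 6 was -0.278 (day 10, -0.565 and -0.641), but days so chosen cannot test slower progress. The lower no-feature share is argued against as the whole cause, since the log2 ratio of pluripotency genes was larger at day 10, with a gap of 6.88 points, than at day 4, with a gap of 14.61, by a median over genes of 1.599. An exchange of EB day 10 replicate 1 and EB day 8 replicate 3 stays open. Correlations higher by 0.319 or more with earlier replicate 1 libraries cannot test it, as those too lay nearer earlier days. A difference in preparation or culture between replicate numbers is open, untested.

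The second pattern is the rise of metallothioneins at EB day 0. Reads shared between paralogs are argued against, because 7 of the 7 called members (8 tested) were at least 2-fold higher in both the count table and the Salmon estimates. A load of zinc or another metal stays open. SLC30A1, a zinc exporter induced by metal and chosen after its values were seen, rose by 1.066 on the log2 scale (SE 0.233, adjusted p = 0.0365, higher in 3 of 3 libraries), from 34.4 ± 4.73 to 71.9 ± 23.0 CPM, but it was as high at day 10 (78.1 ± 18.6 CPM), where MT1G had 1.25 ± 0.51 CPM. Low oxygen and a change of medium are also open and were not tested.

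The third pattern is the rise of 5863 genes by at least 2-fold between days 0 and 10 together with the higher no-feature share. Genomic DNA as cause is argued against for most of them. In the highest day 10 library 381 olfactory receptor genes, silent in most cells, held 0.0541 CPM per kilobase of exon. Of 5304 with a known exon length 5274 rose by more (lower quartile 0.459, 0.404 higher), though the low-count filter and 2-fold rule had favoured such genes. Over 18 EB libraries the receptor sum and the share, as deviations from the day means, correlated at 0.982, so background reads may add to the share. From day 0 to day 10 the sum changed by 0.279 on the log2 scale (SE 0.145), while the share went from 20.92% to 43.24%. Reads of unspliced RNA stay open. Of 582 tested genes lying in introns on the same strand, 325 rose and 21 fell by at least 2-fold (median log2 fold change 1.52, quartiles 0.64 and 2.54), but the summed level of all 860 such genes fell from 1850 ± 117 to 1195 ± 84.3 CPM. The median was 0.89 for antisense genes (quartiles -0.17 and 1.99), 0.51 for lincRNA genes (-0.79 and 1.75) and -0.11 for protein-coding genes. With the replicate block and the no-feature share in the fit, the median log2 fold change of these genes was 1.563 (quartiles 0.897 and 2.583) against 2.166 without them. Of these genes 2828 were still called, and the median SE went from 0.475 to 0.645. Calls ended as folds shrank and as the share, rising with time, widened the errors. A trend with the share and differentiation cannot be told apart, as the design joins them.

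Other splits of the compared libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes called, the real split and the highest other gave 170 and 41 (EB day 0 against iPSC), 8276 and 0 (days 2 and 0), 921 and 0 (4 and 2), 2227 and 0 (6 and 4), 86 and 0 (8 and 6), 3151 and 3388 (10 and 8) and 14892 and 1 (10 and 0). The real count was reached by 1 split, the real one, in each comparison except day 10 against day 8, where 2 splits reached it. The other of these exchanged EB day 8 replicate 3 and EB day 10 replicate 1, and with the replicate block the real groups gave 2770 higher and 2018 lower. For the paired comparisons, the 3 other splits that part all same-numbered pairs called 0 genes by edgeR.

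For gene lists called, the real and highest other counts were 3 and 5 (EB day 0 against iPSC, 4 splits as large), 19 and 9 (days 2 and 0, 1 split), 12 and 10 (4 and 2, 1 split), 13 and 14 (6 and 4, 2 splits; 10 among splits that part all pairs), 15 and 17 (8 and 6, 3 splits), 21 and 20 (10 and 8, 1 split) and 18 and 17 (10 and 0, 1 split). List counts by camera with the preset correlation were thus reached or nearly reached by splits that mix the groups, except for days 2 and 0. In the joint test, 1 of 100 splits reached the real 17052 genes (others up to 6397), so chance is unlikely for independent libraries. For the 907 transient genes 5 of 100 splits gave as many, with up to 2125, so chance cannot be excluded. A structure of the samples may underlie the high counts, which was not tested.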

How the results depend on the processing

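The tests with the no-feature share as a covariate and without all replicate 1 libraries were chosen only after the results were seen. With RLE factors none of the counts of genes, transient genes or lists moved beyond 1.5 times, and with no low-count filter, under which lists were not tested, none of the counts of genes or transient genes did. RLE factors kept 166 of 170 calls for EB day 0 against iPSC, 8210 of 8276, 857 of 921, 2201 of 2227, 85 of 86 and 3128 of 3151 for the successive intervals, and 14812 of 14892 for day 10 against day 0. The joint time course count stayed within 1.5 times under each alternative, from 14818 with Salmon estimates to 19260 with the replicate block, and from 15529 to 18022 with a library left out. Where no cause is named below, the cause was not tested.

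The gene lists depended most on the correlation assumed between genes. Estimated correlations had a median of 0.183 and lay above the preset 0.01 in 33 of 38 lists, which widens the test's errors by construction. With them, 2 of 3 calls remained for EB day 0 against iPSC (1 higher, 1 lower), 1 of 19 for days 2 and 0 (0 higher, 1 lower) and 1 of 21 for days 10 and 8 (1 higher, 0 lower). Camera called 0 higher and 0 lower lists for days 4 and 2, 6 and 4, 8 and 6, and 10 and 0, where 4, 10, 3 and 8 were higher and 0, 0, 5 and 1 lower at an unadjusted p under 0.05. With fry, 8 lists were higher and 0 lower for days 4 and 2 (2 lower at an unadjusted p under 0.05), 0 were lower for days 6 and 4 (2 unadjusted), 2 higher and 1 lower for days 8 and 6, and 18 higher for days 10 and 0.

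With the replicate block, 202 genes rose and 243 fell for EB day 0 against iPSC, 1332 and 908 for days 4 and 2, and 184 and 75 for days 8 and 6, while 1376 fell for days 6 and 4 and 2018 for days 10 and 8. The block gave 128 transient genes peaking at day 8, and 4 lists lower for EB day 0 against iPSC, 5 higher for days 2 and 0 and 4 lower for days 6 and 4. It kept 170 of 170, 8272 of 8276, 921 of 921, 2226 of 2227, 86 of 86, 3150 of 3151 and 14878 of 14892 gene calls. With the no-feature share added to the block, 313 rose and 306 fell for EB day 0 against iPSC, 915 and 577 for days 4 and 2, 2223 and 1641 for 6 and 4, 194 and 93 for 8 and 6, 3110 and 2133 for 10 and 8, and 4075 and 3636 for 10 and 0. It gave 220 transient genes peaking at day 4, 2 lists higher and 5 lower for EB day 0 against iPSC, and 4 lower for days 6 and 4.

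DESeq2 called 238 genes higher and 231 lower for EB day 0 against iPSC, 611 lower for days 4 and 2, and 204 and 90 for days 8 and 6. The stricter filter gave 26 lower for days 8 and 6. Salmon estimates gave 145 lower for EB day 0 against iPSC, 108 and 31 for days 8 and 6, and 270 transient genes peaking at day 4, and 4 lists lower for EB day 0 against iPSC, 6 lower for days 2 and 0 and 5 lower for days 6 and 4. They kept 136 of 170, 5823 of 8276, 713 of 921, 1782 of 2227, 68 of 86, 2612 of 3151 and 10755 of 14892 gene calls, and moved the median of all log2 fold changes by 0.175 for day 10 against day 0. With the compared libraries alone, which leaves 6 libraries to estimate the spread, 1013 rose and 763 fell for days 4 and 2, 226 and 11 for 10 and 8, and edgeR called 0 and 0 for 8 and 6 (628 and 541 at an unadjusted p under 0.05). Of the calls, 69.4% were higher for days 8 and 6 with DESeq2 against 81.4%, and 95.4% for days 10 and 8 with the compared libraries alone.

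Without all replicate 1 libraries, 728 genes rose and 822 fell for EB day 0 against iPSC, 1190 and 768 for days 4 and 2, 249 and 45 for 8 and 6 and 3131 and 3075 for 10 and 8, while 1590 fell for 6 and 4. Transient genes then numbered 268, 690 and 221 at peak days 2, 4 and 8. Lists lower were 5 for EB day 0 against iPSC, 6 for days 6 and 4 and 3 for 8 and 6, and lists higher were 4 for days 2 and 0 and 8 for 4 and 2.

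With 1 library left out, genes higher and lower ranged from 19 to 214 and from 33 to 153 for EB day 0 against iPSC, with the lowest values without iPSC replicate 2 and the highest without EB day 0 replicate 1. They ranged from 2748 to 3827 and 3016 to 3977 for days 2 and 0. For days 4 and 2 they ranged from 194 (without EB day 2 replicate 1) to 583 and from 99 (without EB day 4 replicate 2) to 282. For days 6 and 4 they ranged from 849 to 1293 and 264 to 558, lowest without EB day 6 replicate 2. For days 8 and 6 they ranged from 16 (without EB day 6 replicate 2) to 126 (without EB day 8 replicate 1) and from 1 (without EB day 6 replicate 1) to 14. For days 10 and 8 they ranged from 1032 to 2825 and 244 to 3008, lowest without EB day 10 replicate 2 and highest without EB day 10 replicate 1, and for days 10 and 0 from 6956 to 7869 and 5916 to 7315. Transient genes ranged from 138 to 234, 290 to 586, 170 to 265 and 26 to 184 at days 2, 4, 6 and 8. Lists higher and lower ranged from 1 to 2 and 2 to 4 (EB day 0 against iPSC), 5 to 8 and 8 to 12 (2 and 0), 3 to 11 and 5 to 8 (4 and 2), 10 to 12 and 1 to 7 (6 and 4), 5 to 12 and 6 in each case (8 and 6), 11 to 14 and 8 to 10 (10 and 8), and 9 to 12 and 8 in each case (10 and 0). Without EB day 8 replicate 1, 7 of the 15 list calls for days 8 and 6 remained. Leaving out a library leaves 2 in its group.

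Of 289 changes of named genes, 203 kept their direction and side of the threshold under every alternative that could test them, and 86 did not under at least 1. Among them, 49 lost the call with the compared libraries alone. SLC5A10 at day 6 against day 0 ranged from -1.59 without EB day 6 replicate 3, the library that held 348 CPM, to 6.57 without EB day 0 replicate 3. HOXA2 at day 6 against day 4 lost its call with Salmon estimates (log2 fold change 1.69 against 3.68), and GLIPR1L1 at EB day 0 did so too (1.89 against 1.99). With the block and no-feature share, SOX2 and DNMT3B at day 10 against day 0 no longer passed, at log2 fold changes of -2.31 and -2.18 against -2.40 and -2.04. At this depth genes with 3 or fewer counts over the libraries of a group allow only a bound or an interval.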

Other observations

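The tests in this part were counts made only after the values were seen, and no hypothesis was tested with them. Among genes at 20 CPM or more in 1 library and at least 8-fold above both other replicates, 20 stood out in the same library in both the count table and the Salmon estimates (4-fold there), and all 20 were in EB day 10 replicate 1. They included ZIC2, at 66.4 CPM against 0.947 and 4.63, and PTPRZ1, at 283 against 3.97 and 26.1, both chosen after their values were seen. In a further 32 cases, some of them the same gene in several groups, a gene stood out in the count table alone. MGAT2, for example, had 778 CPM in iPSC replicate 2 against 0.67 and 0.249, while the Salmon estimates gave 25.5, 26.5 and 27.2 CPM.

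Some lists not called by camera had members that passed in both directions. In neural crest genes 7 of 14 rose and 6 fell between days 0 and 10 (camera adjusted p = 0.599). In endothelium and blood progenitors 5 of 14 rose and 2 fell between days 8 and 10 (camera adjusted p = 0.109), and the endothelial cadherin CDH5 rose from 1.28 ± 0.18 to 13.5 ± 4.9 CPM.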
